A study of Mus musculus with 4 samples.

How the data were processed

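RNA that came down with an antibody against 4E-T, or with control IgG, was sequenced from the ventricular-subventricular zone (V-SVZ) of wild-type CD1 mice at postnatal day 7 or 8. The V-SVZ is the stem cell niche that lines the lateral ventricles of the forebrain. 4E-T is the protein made by Eif4enif1, which binds the cap-binding protein eIF4E and localises to P-bodies, cytoplasmic granules of RNA and protein. There were 2 libraries per group, one of each antibody in each of 2 numbered experiments. Per the labels' protocols, RNA was isolated with a MAGNA RIP kit, cDNA was made with the SMART-Seq v4 low-input kit and libraries with the Nextera XT kit. Nothing in the labels states whether the experiments used separate animals or litters, so p-values measure only the spread between these samples, which may be technical.

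The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2, DESeq2 1.26.0 and DESeq, and the mouse build mm10. The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of 35147 genes with versioned Ensembl identifiers and symbols. It gives FPKM for each of the 4 libraries as deposited by the authors. Per the file headers, it also holds the authors' DESeq2 comparison of 4E-T with IgG, which includes a mean normalized signal per gene over all libraries. The authors' columns further hold a log2 fold change with its standard error, a Wald score, a p-value and adjusted p-value, and a linear fold change. The model behind the authors' comparison, and whether it used the experiment number, is not given in the sources used here. Values from that comparison are printed as the authors' own.

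Within a gene, the FPKM of the libraries are whole multiples of what 1 read is worth. With the authors' deposited mean signal this gave back a read count for every gene and library, and 100% of values were whole within a tolerance of 0.001. The lowest total of a gene over the 4 libraries was 10 reads. The recovered reads gave the depth of each library and an additional test. The sum that served as the per-million denominator of the FPKM is not given in the sources used here. Gene reads per unit of that denominator, set to 1 in IgG replicate 1, were 1.671 in IgG replicate 2, 1.432 in 4E-T replicate 1 and 1.84 in 4E-T replicate 2, so the scale of the deposited FPKM differs between libraries.

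The test followed the branch fixed for normalized values before the data were examined. Genes with a mean FPKM of at least 1 over the 4 libraries (17651 genes) were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with antibody as the only term. Empirical Bayes moderation used a trend and was robust, the test was two-sided, and calls had a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The branch fixed for counts was not used, because the values tested are FPKM.

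A fit with the experiment number as a block was fixed in advance as an alternative. Libraries of the same experiment deviated together from their group means, with a correlation across genes of 0.67 on the deposited FPKM and 0.49 after quantile normalization. The titles give each pair of libraries a shared experiment number, read here as a shared batch, so the numbers were taken to pair the samples. Values of the blocked fit are therefore printed wherever they change a call. That fit leaves 1 residual degree of freedom and rests on a spread shared across genes. A further fit was added after seeing the data: limma-voom on the recovered reads, scaled by trimmed mean of M-values (TMM; log-ratio trim 0.3, sum trim 0.05), with the experiment block. It is called the read-based fit with the block.

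The tests were run on simulated data built for the comparison of 4E-T with IgG, with 18262 genes, a dispersion of 0.04 and experiment effects. Both libraries of an experiment were given the same effects, so the simulation assumes the pairing and cannot test whether a block is right. Of 98 genes changed 2-fold and 99 changed 4-fold, the fit without a block found 0% and 0%. The blocked FPKM fit found 43.9% and 100%, and also called 87 unchanged genes beside 142 changed ones. The read-based fit with the block found 36.7% and 100%, and called 8 unchanged genes beside 135 changed ones. Simulated FPKM were scaled by each library's own gene reads, unlike the deposited FPKM, and the dispersion was a set value. These error counts need not hold for the deposited data.

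A total of 24 gene lists were fixed before the data were examined. Each was tested with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation and directional fry were alternatives. The estimated correlation rests on 2 residual degrees of freedom, or 1 with the block or with a library left out, so it can hardly pass. The preset correlation treats the members of a list as nearly independent, so its p-values may be far too small. Neither version of camera settles whether a list shifted. Counts of called members are given over all genes tested and adjusted over the list alone. Medians of lists are given relative to the median of all tested genes, because scaling moved the latter.

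The rule for named genes was fixed as follows. In each direction it takes the 10 genes with the largest absolute log2 fold change among those with adjusted p under 0.05, the same direction in both experiments and a mean FPKM of at least 5. Gm, Rik, pseudogene and accession names are left out. If none passes, it takes the 10 with the smallest p, described as not passing. From each list it takes the 4 called members with the smallest p, or 2 where none passes, and it always includes Eif4enif1. No qualifying gene passed without the block, so the same rule was also applied to the blocked fit, a choice made after seeing the data. Some genes that the rule takes are not reported here.

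Alternatives were the block, leaving out each library, no filter, a mean FPKM of at least 5, a pseudocount of 0.1, quantile normalization, an adjusted p under 0.1 and a 2-fold minimum. Combinations with the block, and the recovered reads, were added after seeing the data. Intervals on shares and ratios of reads are exact binomial (Clopper-Pearson) at 95% and cover counting error only. Bootstrap intervals of list medians come from 2000 draws of the genes of a list. They treat genes as independent and hold no spread between libraries. No test of outlying samples was made in groups of 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.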

Results

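The comparison asks which RNAs of the postnatal V-SVZ are found with 4E-T, a repressor of translation, beyond the level that control IgG brings down. The recovered gene reads numbered 14421019 in IgG replicate 1, 24780150 in IgG replicate 2, 23006357 in 4E-T replicate 1 and 28749439 in 4E-T replicate 2. Across the 17651 tested genes, Pearson's r of log2(FPKM + 1) was 0.973 between the 4E-T libraries and 0.922 between the IgG libraries. IgG replicate 2 was closer to the 4E-T libraries than to IgG replicate 1, with r of 0.947 with 4E-T replicate 2 and 0.926 with 4E-T replicate 1. The number of genes at 0 reads was 77 in IgG replicate 1, 676 in IgG replicate 2, 442 in 4E-T replicate 1 and 2689 in 4E-T replicate 2. Olfactory and vomeronasal receptor genes (1102 genes), which belong to sensory neurons of the nose, took 0.214% of the reads of IgG replicate 1 (95% interval 0.212 to 0.217). The same share was 0.0376% (0.0369 to 0.0384) in IgG replicate 2, 0.0498% (0.0489 to 0.0507) in 4E-T replicate 1 and 0.0126% (0.0122 to 0.013) in 4E-T replicate 2.

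RNAs of chromatin regulators, zinc finger proteins and cell division genes stood higher in 4E-T than in IgG precipitates, and RNAs of vascular cells stood lower, by list tests that did not pass with an estimated correlation (limma camera, adjusted p = 0.972 with an estimated correlation for each list). All 24 lists fixed in advance had that value, so the estimated correlation could not tell shifted lists from the others. The vascular difference lay mostly in experiment 1, with a median relative to all genes of -1.66 there and -0.22 in experiment 2. Cenpe, which encodes a kinetochore motor, had 7.39 ± 0.661 FPKM in IgG and 41.8 ± 14.1 in 4E-T (SD, n = 2 libraries per group here and below). Zfp57, a zinc finger protein that maintains genomic imprints, had 23.8 and 17.41 FPKM in the IgG libraries and 104.62 and 115.24 in the 4E-T libraries. Itm2a, a transmembrane protein gene, went the other way, with 47.0 ± 10.5 FPKM in IgG and 14.8 ± 4.01 in 4E-T. Without a block, limma called 1 gene higher and 0 lower. At an unadjusted p under 0.05 there were 1982 genes higher and 315 lower. With the experiment number as a block, limma called 3090 of the 17651 genes higher and 784 lower. That fit took the spread of most genes from a trend across genes, so its very small p-values do not measure how a single gene varied. In the simulation it called 87 unchanged genes beside 142 changed ones. Counts of called members within lists are to be read beside the shares of all genes called.

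The gene called without a block was Gm22571, a predicted gene outside the naming rule and chosen after its values were seen. It had 1 read in each IgG library and 23 and 17 reads in the 4E-T libraries, a ratio of shares of 15.1 (95% interval 3.93 to 129). Its log2 fold change was 2.98 (SE 0.31, limma adjusted p = 0.046). The call was lost without a block when no filter, quantile normalization, or recovered reads and TMM were used, as 0 genes were called there. The balance of calls under the block depended on scaling. Of the calls on the deposited FPKM 79.8% were higher, against 53.1% after quantile normalization (1843 higher, 1630 lower) and 55.3% in the read-based fit (2400 higher, 1941 lower). The median log2 fold change of all genes moved from 0.18 to -0.01 with quantile normalization. The read-based fit with the block shared 2376 of the 3090 higher and 606 of the 784 lower calls, and 0 genes were called in opposite directions. Leaving out IgG replicate 1, in a fit without a block, gave 858 higher and 157 lower, and leaving out IgG replicate 2 gave 2441 and 1094. The counts were 2 higher and 4 lower without 4E-T replicate 1, and 2 and 0 without 4E-T replicate 2. The authors' deposited table gave an adjusted p under 0.05 to 2456 genes higher and 597 lower, or 80.4% higher. Of the blocked calls, 2415 higher and 164 lower were also called in the authors' deposited table.

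**Figure D1:**
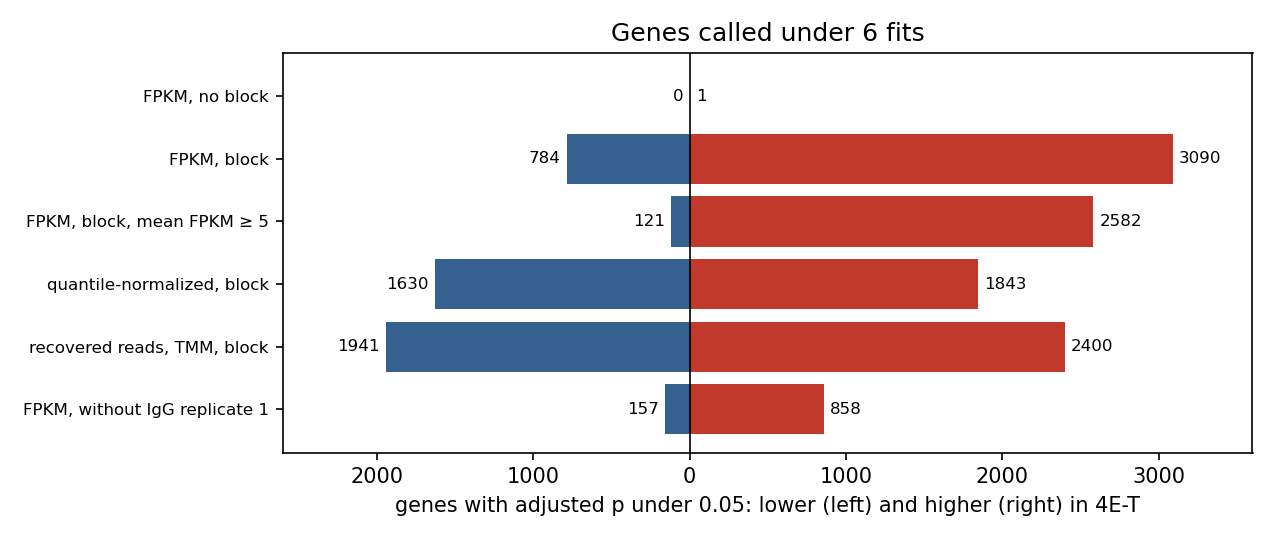
Number of genes with limma adjusted p under 0.05 under 6 fits, with genes lower in 4E-T drawn to the left of 0 and genes higher to the right. The FPKM fit without a block called 1 gene, the blocked FPKM fit 3090 higher and 784 lower, and the blocked read-based fit 2400 higher and 1941 lower.

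Among the 10 higher genes with the largest blocked change were Zscan18, Zfp57, Cenpe, Srrm1, Rsrp1, Pclo and Kin. Zscan18, a zinc finger gene, had 6.33 ± 0.452 FPKM in IgG and 38.1 ± 12.5 in 4E-T. Its log2 fold change was 2.38, with limma adjusted p = 7.42e-15 with the block and 0.202 without. The log2 fold change of Zfp57 was 2.37 (limma with the block, SE 0.30, adjusted p = 3.02e-12), and that of Cenpe was 2.31 (SE 0.28, adjusted p = 1.19e-13). Srrm1, a coactivator of splicing, had 34.4 ± 2.58 FPKM in IgG and 168 ± 11.4 in 4E-T, and Rsrp1, an arginine- and serine-rich protein gene, a log2 fold change of 2.20. Pclo, which encodes a presynaptic scaffold protein, had a log2 fold change of 2.20, and Kin, a DNA- and RNA-binding protein gene, 2.17. Erdr1, at 2.62, has near-identical copies that can share reads, so its value is uncertain. Snora41, a small nucleolar RNA, rested on 5 IgG and 66 4E-T reads, a ratio of shares of 10 (95% interval 4.07 to 31.8), and Mir1968 on 10 and 56 reads, a ratio of 4.24 (2.14 to 9.32). Both small RNAs can share reads with a host gene. The rule took these 10 genes because they passed in the blocked FPKM fit and were higher in both experiments. All of them also passed in the blocked read-based fit.

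Without the block, the rule's 10 higher genes with the smallest p did not pass, each at a limma adjusted p of 0.202. They were Snora41, Zrsr1, Snord65, Zscan18, Hist1h1e, Pclo, Cenpe, Zfp11, Zfp354a and Mir1968. Zrsr1, a retroposed relative of a splicing factor gene, had 4.16 ± 0.41 FPKM in IgG and 21.5 ± 2.41 in 4E-T, and shared reads with its relative cannot be ruled out. Snord65 had 5 IgG and 28 4E-T reads, a ratio of shares of 4.24 (1.62 to 14.1), and did not pass in the read-based fit with the block (limma adjusted p = 0.0536).

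Lower in 4E-T with the block were Cacfd1, Itm2a, Ly6c1 and Arf3, along with n-R5-8s1 and small or segment genes of few reads. Cacfd1, a calcium channel flower domain gene, had 80.45 and 140.21 FPKM in the IgG libraries and 34.30 and 33.38 in the 4E-T libraries. Its log2 fold change was -1.62 (limma with the block, SE 0.30, adjusted p = 4.29e-06). The log2 fold change of Itm2a was -1.61 (SE 0.29, limma adjusted p = 1.43e-06), and that of Arf3, a small GTPase of the Golgi, was -1.25 (SE 0.31, adjusted p = 0.000735). Arf3 rested on IgG replicate 2: it was at -0.51 without that library (limma adjusted p = 0.458) and at -1.98 without IgG replicate 1. Ighd5-1, an antibody gene segment, had 9 IgG and 2 4E-T reads, a ratio of shares of 0.168 (95% interval 0.0177 to 0.813). The ratios were 0.181 (0.0846 to 0.355) for Mir3099, 0.265 (0.0947 to 0.653) for Mir3961 and 0.243 (0.101 to 0.531) for the T cell receptor segment Traj45. The mitochondrial tRNA gene mt-Ta had a log2 fold change of -1.72, and n-R5-8s1, a repeated ribosomal RNA gene whose copies can share reads, -1.23. mt-Ta was at -0.88 without IgG replicate 2, n-R5-8s1 at -0.66 without 4E-T replicate 2, Traj45 at -0.41 and Mir3099 at -1.02 without IgG replicate 1. Without 4E-T replicate 2, Ighd5-1 was at -1.14 and Mir3961 at -0.72. Without the block, the 10 lower genes with the smallest p, which added Vwa1, Slc7a1 and Cldn5, did not pass, and Vwa1 went from -1.19 to -0.78 without IgG replicate 1. After quantile normalization with the block, Itm2a (limma adjusted p = 0.113), Ly6c1 (adjusted p = 0.158), Traj45 (adjusted p = 0.326), Vwa1 (adjusted p = 0.0987) and Cldn5 (adjusted p = 0.219) did not pass.

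**Figure D2:**
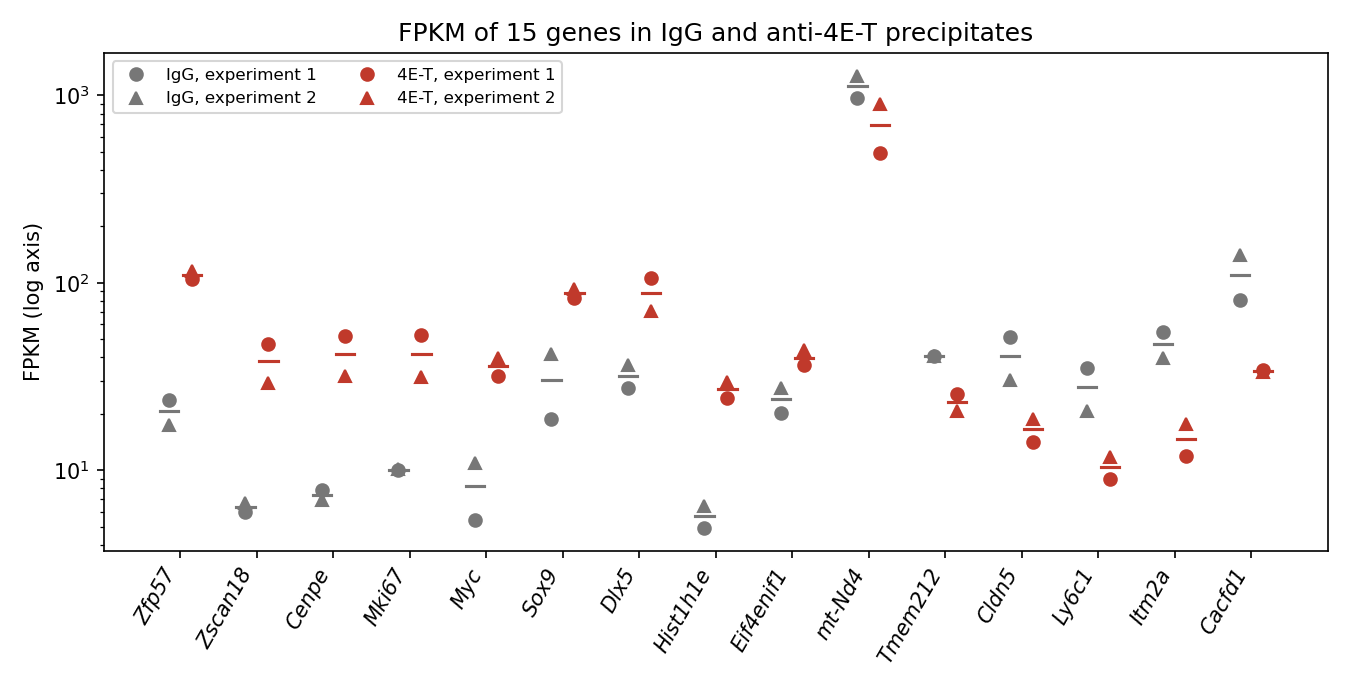
FPKM (log axis) of 15 genes in each library, in grey for IgG and red for 4E-T, with circles for experiment 1, triangles for experiment 2 and short lines for group means. Cenpe stood at 7.39 FPKM on average in IgG and 41.8 in 4E-T, and Itm2a at 47.0 and 14.8.

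Chromatin regulators stood higher as a group: 86 of 87 measured members had a log2 fold change above 0, and their median lay 0.57 above that of all genes. With the block 47 rose and 0 fell (54 and 0 adjusted over the list alone), and the read-based fit with the block called 39 higher and 0 lower, and quantile normalization with the block 34 and 1. Smarcc2, a subunit of BAF chromatin remodelling complexes, had 51.0 ± 17.6 FPKM in IgG and 166 ± 21.6 in 4E-T, a log2 fold change of 1.72 (limma with the block, adjusted p = 1.27e-06). Crebbp, an acetyltransferase gene, had a log2 fold change of 1.45, and of 0.83 without IgG replicate 1. Ring1, a Polycomb protein gene, had a log2 fold change of 1.28. The list shifted by camera (limma adjusted p = 9.16e-09), also without IgG replicate 1 (adjusted p = 0.00696), but not with an estimated correlation (adjusted p = 0.972 with an estimated correlation, and 0.991 without IgG replicate 1).

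Genes named Zfp shifted as well (357 tested of 396 in the table; camera in limma, adjusted p = 7.84e-10), with a median 0.31 above that of all genes. The call was lost at adjusted p = 0.972 with an estimated correlation. With the block 131 rose and 0 fell (148 and 0 adjusted over the list alone), and the read-based fit with the block called 111 higher and 5 lower, and quantile normalization with the block 73 and 4. Besides Zfp57, Zfp11 had 3.76 ± 0.564 FPKM in IgG and 16.2 ± 1.98 in 4E-T, Zfp354a a log2 fold change of 1.78 and Zfp804a one of 1.79. Related Zfp genes can share reads, so single members are uncertain.

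Cell cycle genes stood 0.40 above all genes at the median of 50 members (camera in limma, adjusted p = 1.26e-05), a call lost at adjusted p = 0.972 with an estimated correlation. With the block 22 rose and 0 fell (25 and 0 adjusted over the list alone), while the read-based fit with the block called 21 higher and 4 lower, and quantile normalization with the block 21 and 3. Without the block 15 were higher when adjusted over the list alone. Mki67, a marker of dividing cells, had 10.1 ± 0.0421 FPKM in IgG and 41.9 ± 15.1 in 4E-T, and Tpx2, a spindle assembly factor, 9.95 ± 2.16 and 44.1 ± 9.86. Kif20b, a kinesin of cytokinesis, had a log2 fold change of 1.59 (limma with the block, adjusted p = 5.9e-08).

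Immediate-early and stress genes had a median 0.41 above all genes over 37 members (camera in limma, adjusted p = 0.0118), but not without IgG replicate 1 (adjusted p = 0.423) and not with an estimated correlation (adjusted p = 0.972 with an estimated correlation). With the block 14 rose and 0 fell (16 and 0 adjusted over the list alone), and the read-based fit with the block called 13 higher and 1 lower, and quantile normalization with the block 10 and 0. Myc had 8.20 ± 3.92 FPKM in IgG and 35.8 ± 5.69 in 4E-T, Egr1 17.7 ± 12.5 and 65.8 ± 27.5 (log2 fold change 1.96, and 1.21 without IgG replicate 1), and Junb and Zfp36 log2 fold changes of 1.88 and 1.46. Histone genes had a median 0.32 above all genes over 40 members (camera in limma, adjusted p = 0.0126), again lost at adjusted p = 0.972 with an estimated correlation. With the block 13 rose and 0 fell (13 and 0 adjusted over the list alone), against 4 higher and 0 lower in the read-based fit with the block and 6 and 2 after quantile normalization with the block. The 4 of 40 were a lower share than the 2400 of 17651 among all genes in the read-based fit. Summed reads of the list did not rise, at 0.247% and 0.233% of gene reads in IgG replicates 1 and 2 and 0.229% and 0.217% in 4E-T replicates 1 and 2. The linker histone gene Hist1h1e had 5.66 ± 1.07 FPKM in IgG and 27.0 ± 3.79 in 4E-T, and Hist1h1b, Hist1h1a and Hist1h2bg log2 fold changes of 1.5, 1.24 and 0.98, the last 0.62 without 4E-T replicate 2 and not passing in the read-based fit with the block (limma adjusted p = 0.0594). Histone genes of a cluster can share reads and are uncertain singly.

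Vascular and mural markers had the lowest median, 0.88 on the log2 scale under that of all genes, or -0.88 (14 members; camera in limma, adjusted p = 1.7e-08), a call lost at adjusted p = 0.972 with an estimated correlation. With the block 0 rose and 7 fell (0 and 9 adjusted over the list alone), the read-based fit with the block called 11 lower, and quantile normalization with the block called 1. Ly6c1 had 27.8 ± 10.1 FPKM in IgG and 10.4 ± 1.9 in 4E-T, and Cldn5, a tight junction protein of brain endothelium, 40.9 ± 14.8 and 16.5 ± 3.23. Pecam1, an adhesion molecule of endothelium, had a log2 fold change of -1.01 and Ly6a one of -0.79, against -0.45 and -0.15 without IgG replicate 1 and -1.56 and -1.44 without IgG replicate 2. Ly6a did not pass after quantile normalization with the block (limma adjusted p = 0.0798). The list took 0.0986% of gene reads in IgG replicate 1, 0.0422% in IgG replicate 2, 0.0281% in 4E-T replicate 1 and 0.0337% in 4E-T replicate 2. Without IgG replicate 1 it shifted in the same direction (limma camera adjusted p = 0.0283), but not with an estimated correlation in that fit (adjusted p = 0.991).

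Mitochondrially encoded mRNAs stood at a median of -0.78 relative to all genes over 10 members (camera in limma, adjusted p = 0.000817). This shift did not pass with an estimated correlation (adjusted p = 0.972 with an estimated correlation), nor after quantile normalization with the block (adjusted p = 0.338). No member passed singly with the block, 6 were lower in the read-based fit and 1 after quantile normalization with the block. mt-Nd4 had 1120 ± 214 FPKM in IgG and 697 ± 291 in 4E-T, and mt-Co3 4.43 ± 0.375 and 2.51 ± 0.398; nuclear copies of mitochondrial sequence can share their reads. Nuclear-encoded respiratory chain genes lay at -0.20 relative to all genes over 79 members (camera in limma, adjusted p = 0.0245, and adjusted p = 0.972 with an estimated correlation), although their mean log2 fold change was 0.02 and their median -0.02. With the block 0 rose and 0 fell, the read-based fit with the block called 11 lower, and quantile normalization with the block called 1 higher and 30 lower. Sdhb and Ndufv3 had log2 fold changes of 0.72 and 0.61 that did not pass on the deposited FPKM, and of 0.26 and 0.34 without IgG replicate 1. Sdhb passed after quantile normalization with the block (log2 fold change 0.46, limma adjusted p = 0.0436).

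**Figure D3:**
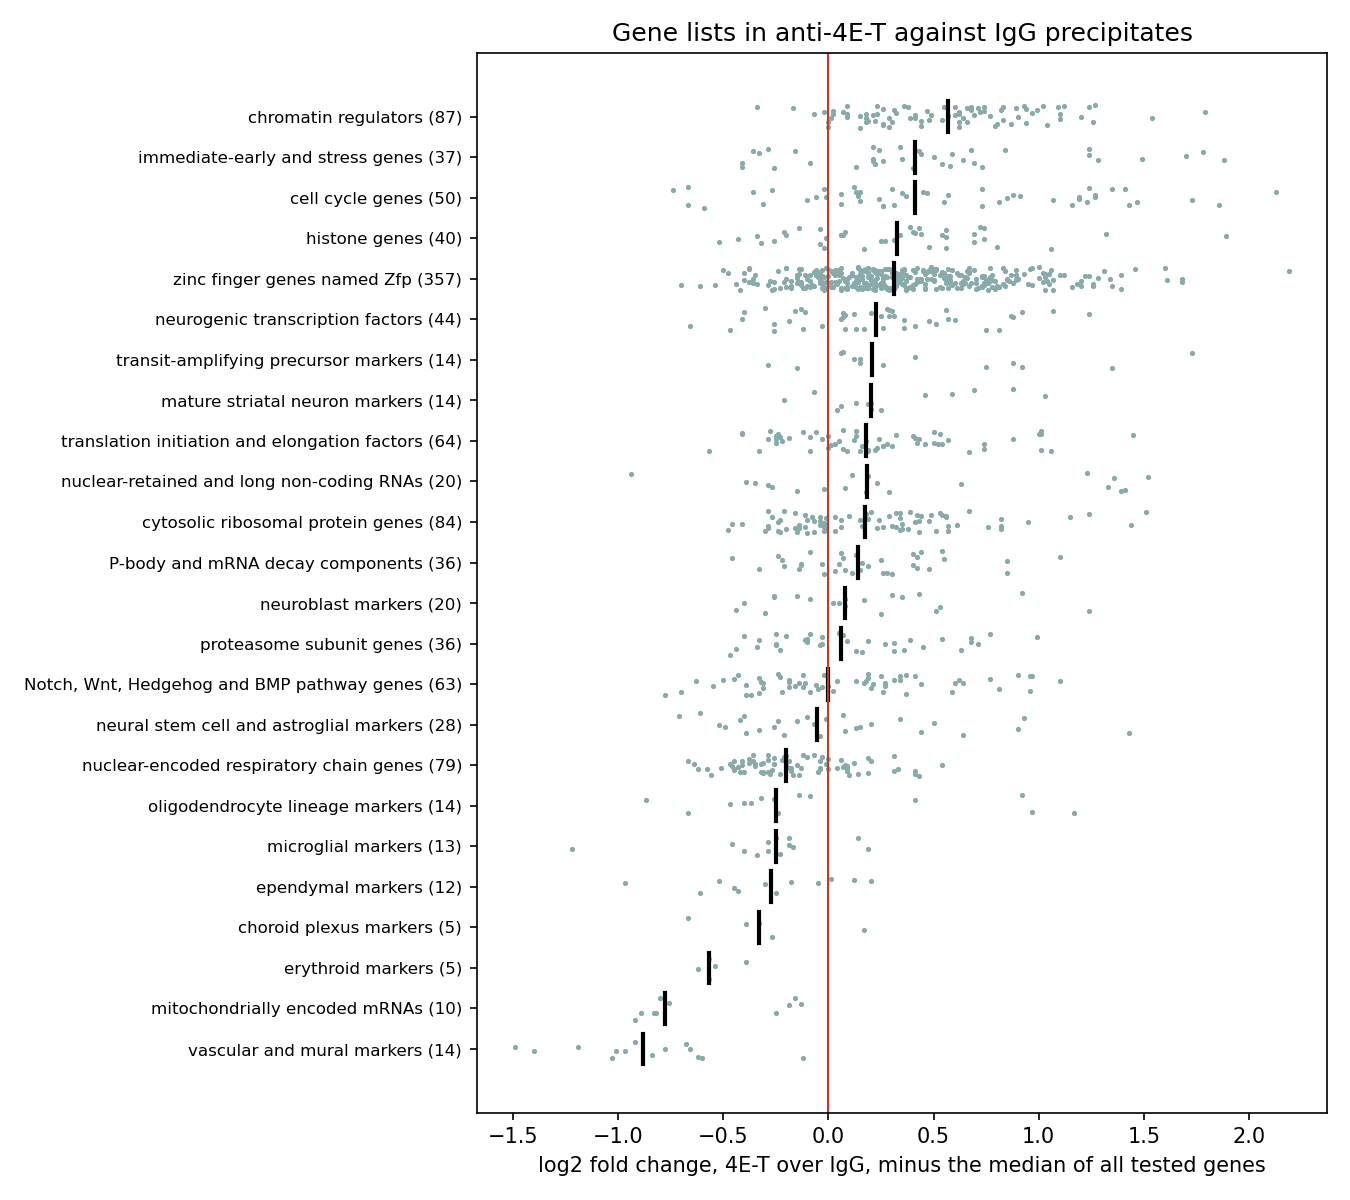
Log2 fold change of 4E-T over IgG minus the median of all tested genes for the members of 24 gene lists, each dot a gene, black bars the list medians, and the number tested in parentheses. Chromatin regulators have the highest median, at 0.57, and vascular and mural markers the lowest, at -0.88.

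Markers of the V-SVZ lineage did not pass as lists over all 4 libraries without the block, although single members passed with it. Without IgG replicate 1, the neural stem cell and oligodendrocyte lists shifted lower (limma camera adjusted p = 0.0141 and 0.0189), calls lost at adjusted p = 0.991 with an estimated correlation in that fit and at adjusted p = 0.972 with an estimated correlation over all 4 libraries. Transit-amplifying precursor markers (14 tested) had limma camera adjusted p = 0.0581 without and 0.0343 with the block. The blocked call was lost at adjusted p = 0.968 with an estimated correlation, and the list did not pass without IgG replicate 1 (adjusted p = 0.395). In it 5 members rose with the block (5 adjusted over the list alone), among them Mki67, Top2a, Gsx2 and Olig2, against 5 higher and 0 lower in the read-based fit and 5 and 1 after quantile normalization with the block. Top2a, also a cell cycle gene, had 22.6 ± 5.42 FPKM in IgG and 66.2 ± 0.422 in 4E-T. Of 28 neural stem cell and astroglial markers 4 rose with the block (4 adjusted over the list alone) and the list did not pass over all 4 libraries (limma camera adjusted p = 0.726). They were the transcription factor genes Sox9, Sox2, Hes5 and Hes1, and Sox9 had 30.2 ± 16.2 FPKM in IgG and 87.8 ± 6.38 in 4E-T. Without IgG replicate 1 the log2 fold change of Sox9 went from 1.61 to 1.06, that of Sox2 from 1.11 to 0.72 and that of Hes1 from 0.82 to 0.54. Hes1 did not pass after quantile normalization with the block (limma adjusted p = 0.0602). The read-based fit with the block called 4 of these markers higher and 4 lower, and quantile normalization with the block 3 and 7. Of 20 neuroblast markers 3 rose (3 adjusted over the list alone), among them Dlx5 and Dlx6, with log2 fold changes of 1.42 and 0.69, against 2 higher and 1 lower in the read-based fit and 2 and 3 after quantile normalization with the block. Dlx6 did not pass in either of these (limma adjusted p = 0.0997 in the read-based fit and 0.286 after quantile normalization). Oligodendrocyte lineage markers had 3 of 14 higher (3 adjusted over the list alone), Bcas1, Sox10 and Olig2, against 3 higher and 2 lower in the read-based fit and 3 and 5 after quantile normalization with the block. Without IgG replicate 1 their log2 fold changes went from 1.35 to 0.85, from 1.15 to 0.65 and from 1.1 to 0.62. Neurogenic transcription factors had 12 of 44 higher and 0 lower (12 adjusted over the list alone), led by Rest, Dlx5, Gsx2 and Tshz1, against 9 higher and 1 lower in the read-based fit and 7 and 4 after quantile normalization with the block. Rest went from 1.25 to 0.78 and Tshz1 from 1.05 to 0.49 without IgG replicate 1. Limma camera gave adjusted p = 0.719 for the neuroblast list, 0.517 for the oligodendrocyte list and 0.121 for the neurogenic factors. With the block 3090 of all 17651 tested genes were higher, a share that the stem cell and neuroblast markers did not reach.

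Lists of other cell types gave few calls on the deposited FPKM with the block. Mature striatal neuron markers had 4 of 14 higher (4 adjusted over the list alone), Rgs9, Penk, Syt1 and Drd1. The read-based fit with the block called 2, without Syt1 (limma adjusted p = 0.0853) and Drd1 (adjusted p = 0.0645), and quantile normalization with the block also called 2 higher. Without IgG replicate 1, Penk went from 1.06 to 0.35, Syt1 from 0.87 to 0.24 and Drd1 from 0.77 to 0.3, and the median of the list was -0.32. Without 4E-T replicate 2, Penk was at 0.23 and Syt1 at 0.01. The microglial marker Cx3cr1 and the ependymal marker Tmem212 were lower, the only members called of 13 and 12 on this scale, with 1 and 0 adjusted over the list alone. After quantile normalization with the block 7 microglial and 4 ependymal markers were lower, and in the read-based fit with the block 2 and 3. Cx3cr1 had 42.4 ± 32.4 FPKM in IgG and 16.9 ± 0.154 in 4E-T. Its log2 fold change was -0.18 in experiment 1 and -1.9 in experiment 2, and went from -1.04 to -0.19 without IgG replicate 2. Choroid plexus markers (5 tested of 8) and erythroid markers (5 of 6) had 0 called with the block and 0 adjusted over the list alone, against 1 and 4 lower in the read-based fit with the block and 2 and 4 lower after quantile normalization with the block. On the deposited FPKM Ttr had a log2 fold change of -0.49 and Hbb-bs one of -0.44, neither passing with or without the block. Both were lower in the read-based fit with the block (limma adjusted p = 0.00141 and 0.0162). They also passed after quantile normalization with the block (limma adjusted p = 0.000606 and 0.0104). As lists, limma camera gave adjusted p = 0.432 for striatal neurons, 0.121 for microglia, 0.102 for ependymal cells, 0.251 for choroid plexus and 0.0507 for erythroid cells. In the read-based fit with the block the microglial, ependymal and erythroid lists shifted lower (limma camera adjusted p = 0.0173, 0.0407 and 0.0154). These calls were lost at adjusted p = 0.827 with an estimated correlation in that fit, and all 3 lists had adjusted p = 0.972 with an estimated correlation in the FPKM fit without a block. After quantile normalization with the block the same 3 lists were lower (limma camera adjusted p = 6.26e-05, 0.00256 and 0.000566, but adjusted p = 0.801 with an estimated correlation). Without IgG replicate 1 the microglial list was lower (limma camera adjusted p = 0.013, but adjusted p = 0.991 with an estimated correlation).

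Nuclear-retained and long non-coding RNAs had 7 of 20 higher and 1 lower with the block (7 and 1 adjusted over the list alone). For this list limma camera gave adjusted p = 0.118 without and 0.041 with the block. The blocked call was lost at adjusted p = 0.968 with an estimated correlation. Without IgG replicate 1 the list shifted higher (limma camera adjusted p = 0.00617), but not with an estimated correlation (adjusted p = 0.991). The read-based fit with the block called 6 higher and 1 lower, and quantile normalization with the block 4 and 2 (limma camera adjusted p = 0.115). Snhg1 had 6.69 ± 3.04 FPKM in IgG and 23.0 ± 3.09 in 4E-T, and Firre, Gas5 and Snhg11 had log2 fold changes of 1.59, 1.57 and 1.54, of which Snhg11 did not pass after quantile normalization with the block (limma adjusted p = 0.213). Genes of the Notch, Wnt, Hedgehog and BMP pathways had 11 of 63 higher and 0 lower on the deposited FPKM with the block (11 adjusted over the list alone), but 11 higher and 7 lower in the read-based fit and 7 and 6 after quantile normalization with the block. The higher genes included the Hedgehog effectors Gli1 and Gli2, each at 1.14 (Gli2 0.72 without IgG replicate 1), Maml2 at 1.28 and Id2 at 1.15. Ribosomal protein genes had 12 of 84 higher (10 adjusted over the list alone, 10 higher and 2 lower in the read-based fit, 12 and 8 after quantile normalization with the block), such as Rpl4, Rpl35 and Rpl23a, whose processed copies can share reads. Translation factors had 10 of 64 higher (10 adjusted over the list alone, 10 higher and 2 lower in the read-based fit, 9 and 4 after quantile normalization with the block), such as Eif2s2 at 1.63 and Eif5b at 1.19. Proteasome subunits had 6 of 36 higher (6 adjusted over the list alone, 4 higher and 2 lower in the read-based fit, 6 and 4 after quantile normalization with the block), such as Psmc4 at 1.17. The block called 3090 of all 17651 tested genes higher, a share that the pathway, ribosome, translation and proteasome lists did not exceed. These pathway, ribosome, translation and proteasome lists did not shift by camera with or without the block, with limma adjusted p = 0.598, 0.204, 0.121 and 0.84 without it.

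P-body and mRNA decay components did not shift as a list (36 tested, limma camera adjusted p = 0.162). With the block 4 were higher (3 adjusted over the list alone), a lower share than the 3090 of 17651 among all genes. The read-based fit with the block called 3 higher and 0 lower, and quantile normalization with the block 3 higher and 1 lower. Cnot3 and Cnot2, of the deadenylase complex CCR4-NOT, had log2 fold changes of 1.28 and 1.03, the decapping gene Dcp1b 1.03 and Tnrc6a 0.73, the last 0.42 without IgG replicate 1. Tnrc6a did not pass in the read-based fit with the block (limma adjusted p = 0.0678) or after quantile normalization with the block (adjusted p = 0.145). Eif4enif1 itself had 23.9 ± 5.18 FPKM in IgG and 39.9 ± 5.21 in 4E-T. Its log2 fold change of 0.72 did not pass (SE 0.43, limma adjusted p = 0.527, and 0.0585 with the block). The authors' deposited table gave Eif4enif1 a log2 fold change of 0.72 with adjusted p = 0.0501.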

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

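The alternatives with recovered reads, those that combine the block with another choice and the estimated correlation without IgG replicate 1 were chosen after seeing the data. The experiment block, from the pairing of libraries, gave 3090 genes higher and 784 lower against 1 and 0 without it. Added to the block, the counts of higher and lower genes were 1843 and 1630 with quantile normalization, 2400 and 1941 with recovered reads and TMM, 2218 and 2123 with recovered reads and totals, 2582 and 121 with a mean FPKM of at least 5, 2697 and 1863 with no filter, 3057 and 773 with a pseudocount of 0.1, 1342 and 344 with at least a 2-fold difference, and 1650 and 1551 with quantile normalization and the stricter filter. Without the block, limma called 0 and 0 with no filter (1926 and 1042 at an unadjusted p under 0.05), with quantile normalization (1762 and 1257) and with recovered reads and TMM (1982 and 641). The stricter filter called 177 and 8, and fewer genes tested is part of that setting. Leaving out each library gave 2 to 2441 genes higher, 0 to 1094 lower and 6 to 12 shifted lists. The lone library left in a group was there assumed to vary like the other group, and no library could be left out of the blocked fit, which would keep no residual degree of freedom. The shifted lists numbered 8, or 10 with the block, 17 with no filter, 17 with the block and no filter, 13 with the block, recovered reads and TMM, and 0 with an estimated correlation, 0 with the block and an estimated correlation, 0 without IgG replicate 1, with the block, recovered reads and TMM, and with the block and quantile normalization when camera used an estimated correlation, and 0 by fry. Of the 1845 log2 fold changes of 104 named genes under the alternatives, 1844 kept their direction. Much of this was fixed in advance and is no measure of robustness. On the deposited FPKM the block, the filters and the threshold leave a fold change as it is. The rule also took the genes of largest change only if both experiments had the same direction. Ttr went from -0.49 to between -1.18 and 0.2 with a library left out, and was above 0 only without 4E-T replicate 2. The block brought 92 of the named genes past the threshold, added the transit-amplifying and long non-coding lists to the shifted ones and changed no other call among the 24 lists fixed in advance. Of the 93 named genes called with the block, 32 had a log2 fold change that moved by over 1.5 times with 1 library left out, 27 of them without IgG replicate 1. Apart from what the settings themselves fix, the cause was not tested. The planned edgeR and DESeq2 fits were not run because the tested values are FPKM. Depth limits some small RNA genes, which rest on fewer than 10 reads in a group.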

Other observations

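All of the gene families in this part, the block combined with other scaling and the test by single experiments were chosen after the calls had been seen. Adjusted p-values of the splicing, membrane protein and snoRNA families were taken over these added families alone. They were not adjusted together with the lists fixed in advance, so they rest on a smaller set of tests. Quantile normalization without a block and leaving out each library were chosen before any result, but the bounds for scaling, IgG replicate 1 and single experiments were set after those results were seen; the bounds for the receptor genes, for length and level and for the gene families were set before their own results were. The wording of the membrane family hypothesis was separated from the vascular pattern after its result was seen, with its bounds kept.

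Genes of splicing factors and SR proteins had a higher median in 4E-T than any of the lists fixed in advance. Of 62 tested, 48 rose and 0 fell with the block, and the read-based fit with the block called 45 higher and 0 lower. Their median lay 1.01 above that of all genes (log2), with limma camera adjusted p = 1.39e-14, and 1.09e-11 without IgG replicate 1, but adjusted p = 0.603 with an estimated correlation, and 0.555 without IgG replicate 1. Srrm1 and Rsrp1, which prompted the test, were left out. Pnisr, a serine- and arginine-rich protein gene, had 50.7 ± 12.7 FPKM in IgG and 223 ± 1.7 in 4E-T (SD, n = 2 libraries each). Pnn, Arglu1, Luc7l3, Srrm2 and Prpf4b had log2 fold changes of 2.08, 2.06, 1.87, 1.80 and 1.46. Messages of splicing regulators as a class may be held with 4E-T, a hypothesis found and tested on the same libraries. Retained introns were not tested, and the trend with gene length and level was not removed for this list. The list of nuclear-retained and long non-coding RNAs stood higher with the block (limma camera adjusted p = 0.041, and 0.968 with an estimated correlation). It did not pass without the block (limma camera adjusted p = 0.118). The list mixes nuclear-retained with other long non-coding RNAs, so it cannot decide whether nuclear RNA was in the precipitates, which stays open.

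Families of membrane proteins stood lower relative to all genes. The medians of Tmem genes (191), Slc genes (244) and other surface families (184) were each -0.17 relative to all genes. Limma camera gave adjusted p = 0.0463, 0.00672 and 0.00672 over the added families alone, and 0.783 with an estimated correlation. The Tmem value lay close to the threshold and might not pass if adjusted together with the lists fixed in advance, which was not done. The median log2 fold change of all genes was 0.18 on the deposited FPKM, so the families themselves lay near no change. The Tmem shift did not pass in limma camera with the block (adjusted p = 0.0555). It did with quantile normalization and the block (adjusted p = 0.000115) and without IgG replicate 1 (adjusted p = 0.000103), but not with an estimated correlation in those fits (adjusted p = 0.453 and 0.555). On the deposited FPKM with the block, 14 were called higher and 2 lower for Tmem, 13 and 7 for Slc and 11 and 5 for the other surface families. Of all 17651 tested genes 3090 were higher and 784 lower, so each family had smaller shares of both. The read-based fit with the block called 13 higher and 23 lower for Tmem, 9 and 51 for Slc and 8 and 33 for the other surface families. The shift relative to other genes may reflect that these messages are translated at the endoplasmic reticulum, a hypothesis not tested further. Across genes the log2 fold change rose with level (Spearman's rho 0.35) and length (0.23). That trend was not removed for these families, so it stays open as well. snoRNA genes (38 tested) had a median 0.48 above all genes (limma camera adjusted p = 0.000134, and 0.603 with an estimated correlation), with 19 higher and 1 lower under the block but 4 and 1 in the read-based fit. Their reads may belong to the introns of host genes, which was not tested.

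The excess of higher calls under the block, 79.8% on the deposited FPKM, fell to 55.3% with recovered reads and TMM. The choice of scale could therefore account for most of that excess, and TMM or quantile scaling would also remove a real enrichment of many RNAs. The excess was not particular to FPKM, as the authors' comparison had 80.4% higher. Its recovered scaling factors were 0.94 and 0.986 in IgG replicates 1 and 2, and 1.068 and 1.05 in 4E-T replicates 1 and 2. The FPKM denominators, relative to IgG replicate 1, followed them at 1.0, 1.029, 1.114 and 1.084 in that order. Background reads remain a candidate explanation too, since the share on receptor genes of the nose was 4.3 times higher in IgG than in 4E-T in experiment 1 and 2.99 times in experiment 2. No spike-in was used here, so a broad enrichment by 4E-T stays open and untested.

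Chromatin regulator and Zfp genes had median lengths of 3.34 and 1.71 relative to the median of all 35147 deposited genes. The genes tested were not the reference, so these values do not show how long the lists are beside them. Across tested genes the log2 fold change rose with length (Spearman's rho 0.23) and with level (0.35). Removing a joint trend on both left medians of 0.41 (95% bootstrap interval over genes 0.26 to 0.5) and 0.28 (0.21 to 0.33) above all genes. Within these libraries this argues against that trend as the whole cause. Without IgG replicate 1 the medians were 0.41 (0.24 to 0.51) and 0.35 (0.26 to 0.43). This argues against that library alone as the cause, though the comparison then rests on a lone IgG library. Binding of these messages by 4E-T is consistent with what is left. GC content was not tested, and background reads and nuclear RNA in the precipitates stay open.

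Vascular and mural markers had a median of -1.66 relative to all genes in experiment 1 (95% bootstrap interval -1.89 to -1.49) and of -0.22 (-0.46 to -0.01) in experiment 2. Most of the shift therefore sits in the experiment of IgG replicate 1, in which vascular markers took the largest share of reads of the 4 libraries. Whether vascular RNA in that library is the whole source cannot be told apart from a smaller difference in both experiments. The interval in experiment 2 reaches close to 0, and it holds no spread between libraries. Among the markers, Ly6c1 (log2 fold changes of -1.84 and -0.77) and Cldn5 (-1.78 and -0.66) were lower in both experiments.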
